A study of Mus musculus with 2 samples.

How the data were processed

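Chromatin immunoprecipitation followed by sequencing (ChIP-seq) for histone H3 trimethylated at lysine 9 (H3K9me3), a mark of heterochromatin, was made from mouse liver on the day of birth (0 days). The labels give 2 biological replicates, each a pool of livers from animals of both sexes of the strain B6NTac;B6NCrl/Lap. Replicate 1 came from 15 mice and had 3 technical replicates. Replicate 2 had 2 technical replicates, and its number of mice is not given. Fragments had a size range of 300 to 500 bp, per the labels.

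The authors deposited 4 peak lists on the mouse build mm10, per the file notes deposited with the samples. Each replicate has a list of its own. A pooled list was called on both replicates together, and a replicated list was derived by the authors from the pooled list and both replicates' lists. The rule by which a pooled peak was called replicated is not given in the sources used here, and it did not require a peak in each replicate's own list: 1205 replicated peaks overlapped only replicate 1's list, 1702 only replicate 2's and 24 neither. The labels name the same possible control experiment for both replicates, and its data were not analysed here. The peak caller, aligner, filters and peak threshold are not given in the sources used here. Each peak carries the authors' signal value, whose reference level is not stated. It also carries the authors' −log10 p-value and −log10 q-value. These values were used only to rank or filter peaks within a list. Signal values were never compared between lists, but some alternatives and tests applied the same p or q limit to both replicates' lists, which assumes that the limit means the same in each. All deposited peaks had a −log10 p of at least 2, and most had a weak q: 9.45% of the replicated peaks had a q of 0.01 or below (−log10 q of at least 2), and 22.7% a q of 0.05 or below. Read depth is unknown, since the files hold no read counts. No interval given here covers sequencing error: 95% Wilson intervals of shares of peaks, and intervals of ratios of such shares, count peaks as if they were independent. No columns of values per sample were left unused (0 columns).

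Positions were compared with the soft-masked sequence of GRCm38, which is the same build as mm10, and with the GENCODE M21 annotation, which holds 55413 genes, of which 21938 are protein-coding. The tool behind the soft-masking is not stated. Peaks on unplaced and unlocalised scaffolds were left out of the shift tests, the signal bins, the chromosome densities and the naming of genes, which cover chromosomes 1 to 19, X and Y. They are included in the make-up of the pooled and replicated lists and in the comparison of the peaks with the smallest p. Coordinates are counted from 1.

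Chance was measured by a circular-shift permutation test. The peaks of a list were moved together along each chromosome by a random distance, with assembly gaps of at least 1000 bp taken out, 1000 times and two-sided. The smallest p such a test can give is 0.002. The shift keeps the clustering of peaks and of genes. Peaks are not replicates, so a p describes these libraries and not newborn livers in general. With 1 group there was no comparison between groups.

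Overlap between replicates was an overlap of at least 1 bp. It was also counted in 10 bins of each list's own signal value. For annotation, a peak's midpoint was placed in a promoter (1 kb either side of an annotated transcription start), an exon, an intron or between genes, in that order. Soft-masked share, G+C share and the observed over expected ratio of CpG were computed over the bases under peaks. For 28 gene lists, fixed before the data were examined, a member was counted when 1 bp or more of its gene body lay under a replicated peak. Benjamini-Hochberg adjustment covered all 28 lists, the 4 annotation classes or the 3 composition measures. Lists of families (zinc finger genes, olfactory and vomeronasal receptors, clustered protocadherins, Hox, cytochrome P450, UDP glucuronosyltransferase, major urinary protein, serpin A, histone and ribosomal protein genes) were defined by symbol. The other lists were imprinted, germline, pluripotency, neuronal, pancreatic and muscle lineage genes, hepatocyte markers, hepatocyte genes rising after birth, markers of erythroid, Kupffer, endothelial, stellate, cholangiocyte, megakaryocyte and lymphoid cells, housekeeping genes, and the H3K9 methylation machinery. Of the 20 erythroid markers, 18 were found in the annotation, and of the 28 machinery symbols 27 genes were found.

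Genes were named by a rule fixed before the data were examined: genes overlapped by the 10 replicated peaks of highest signal value, 1 peak per gene, the 15 protein-coding genes with the most bases under replicated peaks, and up to 4 members of each list with the most bases under them. Genes of families with near-identical copies are uncertain, since reads can be shared between copies. Overlapping genes share the peaks that lie in both.

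Alternatives fixed in advance were other overlap minimums, a q of 0.01 or below, the 50% of peaks with the highest signal, lists of equal length, merging of peaks within 1 kb, leaving out chromosomes X and Y, each replicate's own list, the pooled list, gene bodies with 5 kb added on each side, promoters alone, at least 500 bp of gene body under peaks, promoters of 5 kb, any overlap in place of the midpoint, ranking by −log10 p, covered bases in place of peak numbers, and 10000 random gene lists matched on length in 20 bins. The random lists drew genes singly and, unlike the shifts, do not keep the clustering of genes that share peaks. Alternatives added after the data were seen were peaks under 50% soft-masked, zinc finger genes without peaks in the last exon, and chromosome density at a q of 0.01 or below. The X chromosome's share in lists of equal length, at a q of 0.01 or below and in the 50% of peaks with the highest signal was also added then.

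The tests were tested on simulated data made from the real annotation. In 100 tests of random lists of 100 genes, with lists reused over several simulated peak sets, 4 gave an unadjusted p under 0.05. Of 10 lists with a planted 2-fold excess, 8 had an adjusted p under 0.05, as had 10 of 10 with a 4-fold excess, and 0 of 10 unplanted lists beside them. Peak sets with 50% of peaks shared gave an overlap of 50.1%, and independent sets gave 0.167%. Simulated background peaks were spread uniformly, list genes were drawn at random, and fewer than 1000 shifts were used. These rates therefore do not cover clustered peaks or lists of neighbouring genes. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.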

Results

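H3K9me3, a histone mark of heterochromatin and of silenced genes and repeats, was mapped by ChIP-seq in mouse liver on the day of birth, in 2 biological replicates of pooled livers from animals of both sexes. Replicate 1 had 31344 called peaks covering 8.64 Mb, and replicate 2 had 58138 peaks covering 15.9 Mb. The pooled list held 16865 peaks, and the authors' replicated list held 11212 peaks covering 3.98 Mb with a median width of 290 bp. Read depth could not be taken from the files. With 1 group, the design allows a comparison of the replicates with each other and a description of where the replicated peaks lie.

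The first question was how far the same regions were marked in both replicates. On chromosomes 1 to 19, X and Y, all of the 10 replicated peaks with the highest signal values, taken 1 per gene, overlapped a peak of each replicate's own list. The replicated list was derived from both replicates' lists, so its selection favoured this overlap, which does not measure agreement of the replicates. The highest signal of the whole replicated list, 12.37, belonged to a peak on an unlocalised scaffold, which is not among these 10. One of them covered 3669 bp of Zfp180 (chromosome 7, 24103941 to 24107609), with its midpoint in a coding exon, and carried a signal value of 6.45. Another lay over the promoter and 5′ UTR of Tcfl5 (chromosome 2, 180642687 to 180643633, signal 6.49), which encodes a transcription factor of the male germline. A peak at Crlf2, which encodes a cytokine receptor subunit, lay in an intron within 1 kb of a transcription start (chromosome 5, 109555206 to 109556653, signal 6.36). The peak of highest signal among the 10 lay between genes on chromosome Y (90740943 to 90742099, signal 7.49), and the next between genes on chromosome 12 (5054915 to 5055358, signal 6.71). Others of the 10 lay at the annotated genes Gm49692, Gm10719, Gm26573 and Gm44973, the last overlapping Zfp865 and Ccdc106. The peak at Gm10719 (chromosome 9, 3017369 to 3017721) was 94.9% soft-masked, so its reads can come from repeated sequence.

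Over chromosomes 1 to 19, X and Y, 9716 of 31157 replicate 1 peaks (31.2%) overlapped a replicate 2 peak, against a mean of 1.29% after random shifts, a 24.25-fold excess. Of replicate 2's 57926 peaks, 9756 (16.8%) overlapped a replicate 1 peak, against 0.694%. Bases covered in both replicates made up 10.1% of the bases covered in either, against 0.231%. Each of these excesses had a permutation p of 0.002, the smallest the shifts can give. Most peaks of either list therefore had no counterpart in the other at the deposited thresholds.

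**Figure D1:**
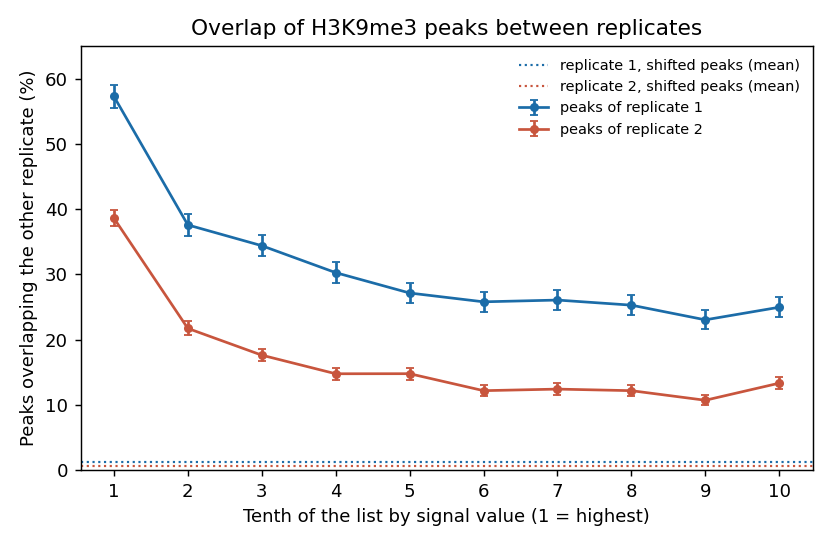
Share of each replicate's peaks that overlap the other replicate (vertical axis, percent) in 10 bins of the list's own signal value (horizontal axis, 1 is highest). Bars are 95% Wilson intervals over peaks and dotted lines the mean of 1000 random shifts; the share falls from 57.3% to 24.97% in replicate 1 and from 38.6% to 13.3% in replicate 2.

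Peaks with high signal were shared more often. In the highest of 10 signal bins of replicate 1, 57.3% of peaks overlapped replicate 2 (95% Wilson interval 55.5% to 59.0%), compared with 24.97% in the lowest (23.5% to 26.5%). In replicate 2 the shares were 38.6% (37.4% to 39.9%) and 13.3% (12.5% to 14.2%). All of the replicated peaks were identical to peaks of the pooled list, of which they made up 66.5%. Of the 11212 replicated peaks, 8281 (73.9%) overlapped a peak of both replicates' own lists, 1205 only one of replicate 1, 1702 only one of replicate 2, and 24 neither.

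The next question was which genes held the replicated peaks. Zinc finger genes, many of which encode repressors of transposable elements, stood out: 126 of 420 (30.0%) held a replicated peak in the gene body, compared with 9.39% after shifts (adjusted permutation p = 0.028). They held 484 of the replicated peaks. The members with the most bases under peaks were Zfp110 (chromosome 7, 12834761 to 12850577), with 9354 bp or 59.1% of the gene, and Zfp873 (chromosome 10, 82048123 to 82064745), with 8875 bp or 53.4%. Zfp981 on chromosome 4 had 8302 bp and Zfp930 on chromosome 8 had 7752 bp. Both replicates' own lists covered these genes: 7347 bp of Zfp110 in replicate 1 and 9070 bp in replicate 2, and 8030 bp and 11271 bp of Zfp873. The excess kept an adjusted permutation p under 0.05 in all 11 alternatives of the gene list test. In the main test and the shift alternatives, this adjusted p passed only because other lists also had a low p. The excess was smaller relative to chance in the replicates' own lists. There the share was 37.1% against 20.4% in replicate 1 and 40.9% against 29.8% in replicate 2. Zinc finger genes are a family with similar sequences, so the share of reads that belongs to each copy is uncertain.

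Imprinted genes, which are expressed from one parental allele, held peaks in 22 of 52 cases (42.3%, against 16.1% after shifts, adjusted permutation p = 0.028). Of the 41 separate regions these genes form, 17 held a peak. The share was 57.7% against 31.2% in replicate 1's own list and 71.2% against 41.2% in replicate 2's. Cdkn1c, which encodes an inhibitor of the cell cycle, had 1891 bp or 69.7% of its gene under peaks (chromosome 7, 143458339 to 143461050), and its highest peak had its midpoint in a coding exon near the transcription start. Kcnq1 and its antisense transcript Kcnq1ot1 shared 4743 bp, and Gnas, which encodes a G protein subunit, had 2474 bp. Members with a peak included Peg3, Snrpn, Plagl1, Grb10, Mest, Nnat and Igf2r. At a q of 0.01 or below the call was lost, with 3 of 52 members (5.77%, against 1.93% after shifts, adjusted permutation p = 0.643).

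Clustered protocadherins, adhesion proteins of neurons encoded in tandem arrays, held peaks in 38 of 57 cases (66.7%, against 21.2%, adjusted permutation p = 0.037). Their gene bodies are nested, and only 9 of 23 separate regions held a peak. Pcdhga1 (chromosome 18, 37661793 to 37841873) had 22 peaks and 10999 bp, nearly all shared with the other gamma genes such as Pcdhga2, Pcdhga3, Pcdhgb1, Pcdhga4 and Pcdhgb2. The readthrough genes Gm42416, Gm37013 and Gm37388, which span the array, had the most bases of all protein-coding genes, from 27774 to 28783 bp. The share stayed above that of shifted peaks in all 11 alternatives, but lost its call in 6 of them. It was 68.4% against 27.4% in the pooled list (adjusted permutation p = 0.0746) and 59.6% against 12.7% in the 50% of peaks with the highest signal (adjusted permutation p = 0.168). At a q of 0.01 or below it was 31.6% against 2.39% (adjusted permutation p = 0.434), and with 5 kb added to genes 77.2% against 23.6% (adjusted permutation p = 0.0559). With at least 500 bp under peaks it was 54.4% against 8.04% (adjusted permutation p = 0.154), and with peaks under 50% soft-masked 64.9% against 19.3% (adjusted permutation p = 0.0839).

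**Figure D2:**
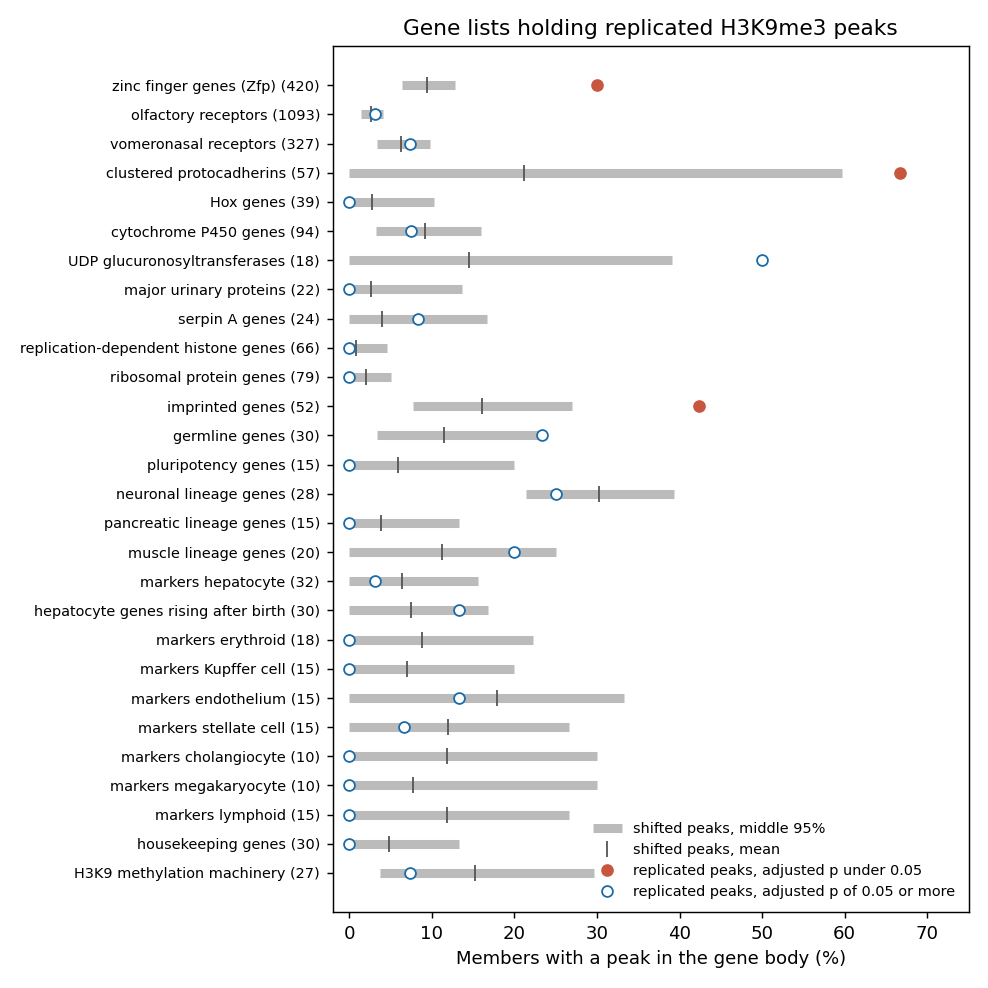
Share of members of each gene list with a replicated peak in the gene body (horizontal axis, percent), with the number of members in brackets. Points are observed shares, grey bars the middle 95% and ticks the mean of 1000 random shifts; zinc finger genes (30.0%), clustered protocadherins (66.7%) and imprinted genes (42.3%) are the filled points.

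UDP glucuronosyltransferases, enzymes that conjugate bilirubin, hormones and drugs, held peaks in 9 of 18 cases, against an expected share of 14.5%, which did not pass after adjustment (permutation p = 0.024, adjusted p = 0.168). It did pass at a q of 0.01 or below, with 7 of 18 (adjusted permutation p = 0.028), and against random lists matched on length (adjusted p = 0.0014). The random lists draw genes singly, so genes that share the same peaks count there as separate hits, and that p is too small. The peaks lay mainly in the Ugt1a cluster, where Ugt1a10 and Ugt1a9 share 6651 bp and Ugt1a5 and Ugt1a8 share 6373 bp (chromosome 1, 88055388 to 88219004 for Ugt1a10). A peak at the shared end of these genes (88217075 to 88217503) had a −log10 p of 13.5 but a signal of 2.74, below the list's median of 2.91. Only 3 of 12 separate regions of the family held a peak. The 9 members counted do not include Ugt1a6a, Ugt1a6b and Ugt1a7c of the same cluster, so the count may not cover the whole cluster. Germline genes held peaks in 7 of 30 cases (23.3%, against 11.5%, adjusted permutation p = 0.548). Over promoters alone the germline count was 5 of 30, against 1.28%, with an adjusted permutation p of 0.0186. At Dazl, which encodes an RNA-binding protein of germ cells, the peak covered the promoter and 5′ UTR (chromosome 17, 50293132 to 50294149). Meioc had 908 bp, Tdrd1 907 bp and Mov10l1 520 bp.

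Among genes of the liver, 1 of 32 hepatocyte markers held a replicated peak, the urea cycle gene Ass1, with 301 bp in an intron. Of the hepatocyte genes that rise after birth, 4 of 30 held one: Cyp2d9 (386 bp, over the promoter), Cyp2c29 (380 bp), Slco1b2 (254 bp) and Cyp2c37 (210 bp). No erythroid (0 of 18), Kupffer cell (0 of 15), cholangiocyte (0 of 10), megakaryocyte (0 of 10) or lymphoid marker (0 of 15) held one. Endothelial markers had 2 of 15 (Stab1 with 313 bp, found in replicate 1's own list and not in replicate 2's, and Stab2 with 245 bp), and stellate cell markers 1 of 15 (Reln, 349 bp). None of these 9 lists differed from shifted peaks, with adjusted permutation p from 0.867 to 1, and lists this short had low expected counts.

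The remaining lists did not differ from shifted peaks either. Ribosomal protein genes (0 of 79), housekeeping genes (0 of 30), Hox genes (0 of 39), histone genes (0 of 66), major urinary proteins (0 of 22), pluripotency genes (0 of 15) and pancreatic genes (0 of 15) held none. Olfactory receptors held peaks in 34 of 1093 cases, vomeronasal receptors in 24 of 327, cytochrome P450 genes in 7 of 94 (Cyp3a57 with 1282 bp) and serpin A genes in 2 of 24 (Serpina9 and Serpina6). Neuronal genes held them in 7 of 28 cases, led by Csmd1 with 7688 bp, and muscle genes in 4 of 20, led by Ttn, the titin gene, with 9913 bp. Of the H3K9 methylation machinery 2 of 27 members held one, Atf7ip (3121 bp) and Smchd1 (356 bp). In replicate 2's own list, ribosomal protein genes (1 of 79, against 8.72%, adjusted permutation p = 0.0224) and the machinery (4 of 27, 14.8% against 44.5%, adjusted p = 0.0187) lay below chance.

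Outside the lists, long genes stood among those with the most bases under peaks. Tmem132d had 46 peaks and 15266 bp (chromosome 5, 127781630 to 128433077), Cdh13 9512 bp and Sdk1 9418 bp. Drg1, which overlaps 2 other protein-coding genes, had 10940 bp in 8 peaks, with the highest signal in an intron (chromosome 11, 3198807 to 3200085). That peak had a −log10 p of 56.2 and a signal value of 2.86, so all 8 lay below the list's median of 2.91.

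**Figure D3:**
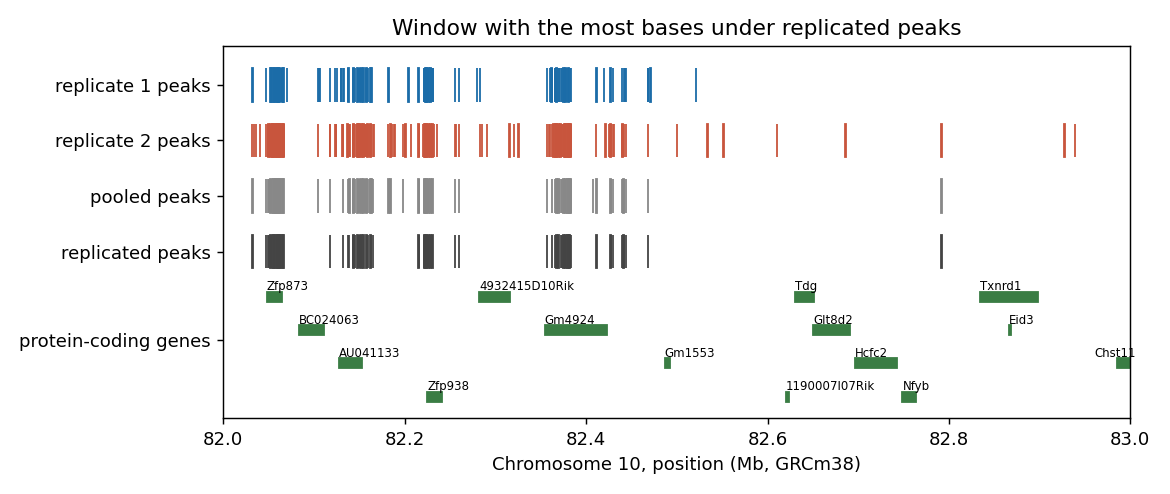
Map of chromosome 10 from 82 to 83 Mb (horizontal axis, Mb on GRCm38), the 1-Mb window with the most bases under replicated peaks. Each box in the upper rows is a peak of replicate 1, replicate 2, the pooled or the replicated list and each green bar a protein-coding gene; the 72 replicated peaks cluster at Zfp873, AU041133, Zfp938 and Gm4924.

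Peaks were clustered along the genome. The 1-Mb window with the most covered bases lay on chromosome 10 from 82 to 83 Mb, with 72 replicated peaks over 38378 bp (41210 bp in replicate 1's list and 54974 bp in replicate 2's). The next lay on chromosome 7 from 12 to 13 Mb, which holds 9 zinc finger genes, with 28303 bp. The window of the Ugt1a cluster on chromosome 1 (88 to 89 Mb) had 27554 bp, and that of the protocadherins on chromosome 18 (37 to 38 Mb) had 26951 bp. Windows with 6 zinc finger genes on chromosome 8 (69 to 70 Mb), 10 on chromosome 4 (147 to 148 Mb) and 7 on chromosome 17 (22 to 23 Mb) followed.

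By annotation, 6.06% of 11061 replicated peaks had their midpoint in an exon outside promoters, against 3.44% after shifts, and 54.5% lay between genes, against 49.8%. Introns held 33.1%, against 40.3%. These 3 classes had an adjusted permutation p of 0.00266. Promoters held 698 peaks (6.31%, against 6.41%, adjusted permutation p = 0.771). They lay below chance in replicate 1's own list (4.79% against 6.29%, adjusted permutation p = 0.002), in replicate 2's (4.14% against 6.29%, adjusted permutation p = 0.00266) and in the pooled list (5.88% against 6.395%, adjusted permutation p = 0.04). The pattern changed with the q-value. At a q of 0.01 or below, promoters held 11.6% (against 6.47%) and exons 14.2% (against 3.48%), while the share between genes was below chance (36.9% against 49.7%), each with an adjusted p of 0.00266. In replicate 2's own list, exons lay below chance, at 3.10% against 3.37% (adjusted permutation p = 0.00799).

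Bases under replicated peaks were soft-masked less often than under shifted peaks, 23.7% against 33.7%, and richer in G+C, 45.5% against 42.0% (adjusted permutation p = 0.003 for both). The aligner and filters are not given, and shifts can move peaks into repeats where reads may not be placed. The lower soft-masked share therefore does not show that the mark avoided repeats. Of the replicated peaks, 86.1% were under 50% soft-masked and 1.21% were over 80% soft-masked. The CpG ratio was 0.199 against 0.194 (adjusted permutation p = 0.0619). It lay below chance in replicate 1's own list (0.176) and replicate 2's (0.167), and above it at a q of 0.01 or below (0.280 against 0.195).

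**Figure D4:**
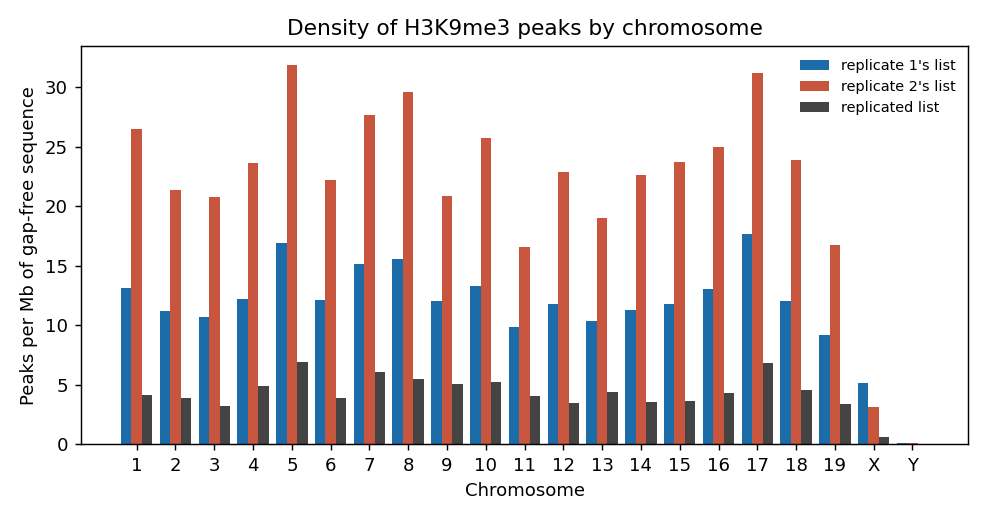
Peaks per Mb of gap-free sequence (vertical axis) on each chromosome (horizontal axis), for the lists of replicate 1, replicate 2 and the replicated peaks. In the replicated list chromosomes 5 (6.88 peaks per Mb) and 17 (6.85) are highest, and chromosome X has 0.575.

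By chromosome, the replicated list was densest on chromosome 5, with 6.88 peaks per Mb of gap-free sequence, and chromosome 17, with 6.85. The order of these chromosomes depended on the measure: chromosome 17 was highest by covered bases (2499 bp per Mb, against 2439 on chromosome 5), at a q of 0.01 or below (0.763 peaks per Mb) and in replicate 1's own list (17.6 peaks per Mb, against 16.9). Chromosome X had 94 replicated peaks, or 0.575 per Mb. That was 0.126 times the autosomal density (95% interval 0.103 to 0.154), and 0.279 times at a q of 0.01 or below. The sequence of X is 46.75% soft-masked, while that of chromosome 3, the most masked autosome, is 35.77%. The density was not adjusted for this or for the sexes in the pools, so it does not show that the mark avoided chromosome X. The replicates differed there. Chromosome X held 841 of replicate 1's peaks (2.70%) and 511 of replicate 2's (0.882%), so that its density relative to the autosomes was 0.407 in replicate 1 and 0.130 in replicate 2. The ratio of the shares was 3.06 (95% interval 2.74 to 3.41, counting peaks only). Whether this difference exceeds the spread between replicates cannot be tested with 1 library each. Of replicate 1's X peaks, 88 (10.5%) overlapped a replicate 2 peak, against 31.7% of its autosomal peaks. Chromosome Y had 7 peaks in replicate 1, 10 in replicate 2 and 5 in the replicated list.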

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

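The peaks on unplaced and unlocalised scaffolds, sequence of the build with no position on a chromosome, entered no test of overlap, annotation, composition, gene lists or density. They are counted in the make-up of the replicated list and in the comparison of the peaks with the smallest p. The replicated list has 151 such peaks on 15 scaffolds, above a floor set at 3. They were flagged because those tests left them out. They cover 97.1 kb, 2.44% of the bases under replicated peaks. Replicate 1 has 187 scaffold peaks and replicate 2 has 212. Their median −log10 p in the replicated list is 7.74, compared with 4.23 on the chromosomes. Their median signal is not higher, at 2.84, compared with 2.91 in the whole replicated list.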

How the results depend on the processing

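The tests of zinc finger genes without last-exon peaks, of peaks under 50% soft-masked, and of chromosome X and density at other thresholds were chosen after the data were seen. The excess overlap of the replicates held in all 19 alternatives. For the results that answer a comparison, 78 alternative values kept their side of the threshold or, where there is no test, stayed within their interval or within 1.5 times a count. Of these, 3 that passed no threshold lay on the other side of chance: the CpG ratio in the pooled list (0.191 against 0.194), and promoters in the 50% of peaks with the highest signal (6.85% against 6.43%) and with peaks under 50% soft-masked (6.55% against 6.398%). Of the others, 16 moved further, 5 reversed, 5 passed the threshold anew and 2 no longer passed it; the cause of these changes was not tested. With an overlap of at least 50% of a peak's own length, the shares in the highest and lowest signal bins were 43.1% and 17.1% in replicate 1 and 26.4% and 8.61% in replicate 2. Ranked by −log10 p they were 59.6% and 21.9%, and 41.2% and 10.5%. Replicated peaks in both replicates' lists made up 72.0% with a 50% overlap and 62.9% at a q of 0.01 or below, where 98.6% of pooled peaks were replicated. At that q the X density ratio was 0.279, and the ratio of X shares was 5.02; with lists of equal length it was 4.04. The CpG ratio was 0.212 in the 50% of peaks with the highest signal and 0.280 at a q of 0.01 or below, both above chance. At that q promoters held 11.6%, introns 37.4% (no longer called) and the space between genes 36.9%; in the 50% with the highest signal the last was 51.6% (no longer called). Promoters held 5.88% in the pooled list, below chance.

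Leaving out 1 replicate leaves the other's own list, with no test among replicates. The CpG ratio was then 0.167 to 0.176, the promoter share 4.14% to 4.79% (below chance), the exon share 3.10% to 3.89%, the X density ratio 0.130 to 0.407, and the number of gene lists called 3 to 5. The overlap of replicates has no such alternative. No paired analysis was possible because there is 1 group. Of the other lists' values, 285 were unchanged in call, 7 lost it and 5 gained it. Depth is unknown, and it limits which weak peaks can be shared.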

Other observations

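The tests on genes active in newborn liver were chosen after the shares of their lists were seen, as were the alternative without last-exon peaks and the soft-masking alternative. The other tests below were set down before their own results were seen, but that of X shares in lists of equal length was added after the data were seen.

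Of 478 replicated peak midpoints in zinc finger genes, 210 lay in the last exon, which encodes the zinc fingers in most of these genes. That is 43.9%, against 17.7% when midpoints were placed at random within the same gene (one-sided permutation p = 1e-04, the smallest the permutations can give). The last exon may thus contribute to the excess at zinc finger genes, but it is not the whole of it: without peaks in last exons, 89 of 420 genes (21.2%) held a peak, against 9.33% after shifts (adjusted permutation p = 0.028). With only peaks under 50% soft-masked, 29.1% of the genes held a peak, against 8.29% after shifts (adjusted permutation p = 0.028). The excess thus did not rest on mostly soft-masked peaks. This filter cannot decide whether interspersed repeats are the source, since 86.1% of all replicated peaks pass it. Soft-masking does not cover similar exons of related zinc finger genes, so reads shared between such copies stay open, and no biological explanation was tested.

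Chromosome X held 2.70% of replicate 1's peaks and 0.882% of replicate 2's. A longer, weaker list in replicate 2 is argued against, since with lists of equal length the ratio of the shares was 4.04 (95% interval 3.48 to 4.70). A few amplified or mismapped regions are argued against too, since the 3 richest 5-Mb windows held 16.5% of replicate 1's X peaks (14.2% to 19.2%), which occurred in 34 of the 35 windows. A larger share of females in the pool of replicate 1 may contribute, but the ratio of the Y shares, 1.30 (0.495 to 3.42), rests on 7 and 10 peaks and leaves it open.

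That the peaks with the smallest p have low signal held for a minority of them. Of the 100 with the smallest p, 25 lay below the list's median signal of 2.91. Of these 25, 10 lay on chromosome 11 between 3101109 and 3200085, in and around Drg1, and 11 on 1 unplaced scaffold. Repeats collapsed in the assembly, with many reads in ChIP and control alike, may explain such peaks: 47 of the 100 lay on scaffolds or were at least 50% soft-masked, compared with 18 of the 100 with the highest signal. The 47 stayed under the majority set as the criterion. Of the 25 with low signal, for which no criterion was set beforehand, 16 lay on scaffolds or were at least 50% soft-masked, compared with 1687 of all 11212 replicated peaks. The 16 were 12 on scaffolds, counted whatever their sequence, and 4 on chromosomes that were at least 50% soft-masked. At most 4 of the 10 on chromosome 11 can therefore be among them. These values go with the explanation mainly for the scaffold peaks. The control's reads were not analysed here, so the explanation stays open.

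Replicate 2's list was 1.86 times as long as replicate 1's. The hypothesis that weak peaks near the threshold made it longer was not borne out: the ratio was 2.10 (95% interval 2.01 to 2.19) at a −log10 p of at least 6, with 6389 peaks against 3041, if p-values mean the same in both lists.

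Genes of lists taken as active in newborn liver rarely held replicated peaks, but expression was not measured here. Lists not taken as active also held none, such as Hox genes (0 of 39) and pancreatic genes (0 of 15), while 3 lists lay above shifted peaks. Of the 157 hepatocyte, erythroid, ribosomal protein and housekeeping genes as 1 list, 1 (0.637%) held one, against 4.21% after shifts (permutation p = 0.028) and 3.55% in random lists matched on gene length (middle 95% 1.27% to 6.37%, permutation p = 0.0466). In replicate 1's own list 2 of them (1.27%) held a peak, against 10.4%, and in replicate 2's 7 (4.46%), against 15.6%, both with a permutation p of 0.002. The lists were joined because each had a low share, while none passed on its own in the replicated list. The p-values of the joined list are therefore too small by an unknown amount. In replicate 2's own list, ribosomal protein genes passed alone (adjusted permutation p = 0.0224). Whether such genes may lack the mark, and whether gene length plays a part, stays open.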
